A study of Mus musculus with 28 samples.

How the data were processed

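The data are Affymetrix array measurements of total RNA from CD45+ cells sorted out of B16.F10 and MC38 tumours of control and Nrp1-deleted mice. Per the labels' protocols, sorted cells were lysed without culture, RNA was extracted with a column kit for small samples, and biotin-labelled cRNA was made by a repeated-cycle amplification, which can distort low-abundance transcripts. The deposited values are on a log2 scale, made by the authors with RMA in Partek 6.6 per the submitters' processing notes. Scanner files were not used here. The version of the RMA background and summary steps is not given in the sources used here.

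The value table held 45141 probe sets, of which 104 were control probe sets. A probe table paired 28898 with 1 gene and 551 with several, and 15588 were unnamed here and were used only as a count. Each of the 17097 genes was represented by the probe set with the highest mean over all arrays, among the probe sets that name it alone, and 7180 genes had several. Of the 23 fixed genes, 19 were measured. The probe table's gene symbols can be old. No pair of arrays was identical, and the highest correlation between any 2 arrays was 0.9957. The root mean square difference between the quantiles of 2 arrays was at most 0.092 (log2) within each of 3 sets and 0.118 to 0.367 between them, as if RMA had been run on each set apart. No comparison of levels across sets can be separated from this. Levels of Xist were low and those of Y-linked genes high on the arrays, with 1 array (MC38 day 18, deleted replicate 1) at a lower Eif2s3y value, 6.47 against 8.74 on its replicate.

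Groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, and choices made later are named as such in the text. A limma model (limma 3.58.1 in R 4.3.3) with a mean for each of the 12 groups was fitted to all 28 arrays, with empirical Bayes moderation and an intensity trend, no filter, and Benjamini-Hochberg adjustment at 0.05. Contrasts were the genotype difference averaged over the 6 settings of tumour and day, over the 3 days of each tumour, and on each day, the difference of these effects between tumours and between day 18 and the first day, day 18 against the first day in each tumour, and MC38 against B16 at days 12 and 18. Adjusted p-values of single genes are from limma unless a permutation test is named, and all tests are 2-sided.

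The named genes are, among those past the threshold whose mean on the higher side lies above the median of all values (3.64), the 10 largest rises and 10 largest falls of each main comparison, and 5 and 5 of each single day or difference of effects. For the means over settings a named gene also had to change in the same direction in every setting averaged. Examples from each list are members with the smallest adjusted p among up to 4, and predicted or clone-named genes were passed over. The measured fixed genes are given for the mean over all settings. They were tested by exchanging genotype labels within tumour and day, exactly over 720 arrangements per tumour and with 100000 draws over both, adjusted over the 19 genes.

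Of 558 genes in 39 fixed lists, 493 were measured. The 38 lists other than the sex-linked one were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, with fry, which asks whether the genes of a list move in a common direction on balance, and, for the genotype means, with the label permutation of the mean list score. The lists hold textbook markers and pathways, and the SREBP lists were included because the study is known to concern lipid metabolism of macrophages. Lists of cell types that lack CD45 were included to look for RNA of such cells, and scores of mixed cells do not count cells. Calls of members are given over all genes tested and adjusted over the list alone.

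The fit was tested on simulated data with 200 changed genes among 17097. For the mean over all settings it recovered 89.6%, 100% and 100% of genes changed by 0.5, 1 and 2 log2 units, with 4.46% of calls false. For MC38 it recovered 61.2%, 95.5% and 98.5% (5.56% false), for MC38 at day 12, with 3 arrays a side, 43.3%, 88.1% and 100% (7.78% false), and for B16 at day 12, with 2 arrays a side, 22.4%, 67.2% and 100% (5.26% false). The last 3 false shares lie above the nominal 5%. In a simulated list that moved, all 4 list tests made the call, and 0 of the 37 other lists were called. The simulated genes varied independently of each other. The simulation therefore cannot show how often the list tests call falsely where the genes of a list vary together. Alternatives covered a filter on dim genes, other ways to treat probe sets, cyclic loess, centring on the 75th percentile, other variance models, array weights, a fit on the compared groups only, a replicate block, leaving out each array, and, chosen after the data were examined, leaving out the B16 day 18 arrays, using melanocytic and fibroblast scores as covariates, setting MC38 day 12 against B16 day 18, and, for the gene lists, cyclic loess, centring on the 75th percentile and control mice alone. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.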

Results

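RNA abundance was measured in leukocytes sorted from mouse tumours by the surface protein CD45, which marks haematopoietic cells. The tumours were grown from B16.F10, a melanoma line, or MC38, a colon carcinoma line. Host mice expressed a Cre recombinase and YFP from Foxp3, the gene for the transcription factor that defines regulatory T cells (Treg). Control mice had an intact Nrp1 gene, and the other mice carried floxed Nrp1 alleles and so lose Nrp1, the gene for the co-receptor neuropilin-1, in Foxp3-expressing cells. Those mice are called Nrp1-deleted here. The 28 arrays form 12 groups. B16 tumours were taken at an early day, at day 12 and at day 18, and MC38 tumours at days 6, 12 and 18. The B16 day 18 and MC38 day 12 groups hold 3 arrays each, and the other 8 groups hold 2 each. The titles place the early B16 arrays at day 8 and the source names place them at day 6, so these arrays are called early. No label says that replicates came from separate mice, so the p-values measure the spread between these arrays, which can be technical.

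The arrays fell into 3 sets by the shape of their deposited values. The B16 day 18 and MC38 day 12 arrays had a mean log2 value of 4.63, the MC38 day 6 and day 18 arrays 4.83, and the early and day 12 B16 arrays 4.96. Every comparison of genotypes at a given tumour and day lay inside a set, as did day 18 against day 6 in MC38 and day 12 against early in B16. Day 18 against early in B16 and MC38 against B16 crossed sets. Differences of the genotype effect between tumours, or between B16 day 18 and the other B16 days, also set effects of different sets against each other. Within groups, arrays correlated at r of at least 0.9885 across probe sets, and the number of arrays limits the precision of every value. Differences below are on the log2 scale, Nrp1-deleted minus control unless another direction is named, with the standard error (SE) after the ± sign.

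Nrp1 itself was lower in every Nrp1-deleted group. In early B16 tumours its log2 values were 9.47 and 9.58 on control arrays against 8.05 and 7.75 on Nrp1-deleted arrays. At day 12 in B16 they were 10.24 and 10.08 against 9.43 and 8.84, and at day 18 9.55, 9.22 and 8.93 against 8.78, 8.36 and 8.32. In MC38 they were 9.06 and 9.16 against 8.93 and 7.97 at day 6, 9.62, 9.64 and 9.53 against 9.34, 9.30 and 9.18 at day 12, and 9.88 and 10.02 against 9.26 and 9.36 at day 18. All deleted arrays of a tumour and day lay below all control arrays of it. The mean difference was -0.84 over the 6 settings (permutation p = 1e-05, the smallest the draws can give, adjusted p = 9.5e-05), -1.13 in B16 and -0.54 in MC38. The probe set can lie outside the floxed part of the gene, and macrophages and dendritic cells also express Nrp1, so this is a weak check of the labels. Foxp3 lay near the background of the arrays and did not pass (difference -0.08, adjusted permutation p = 0.401).

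**Figure D1:**
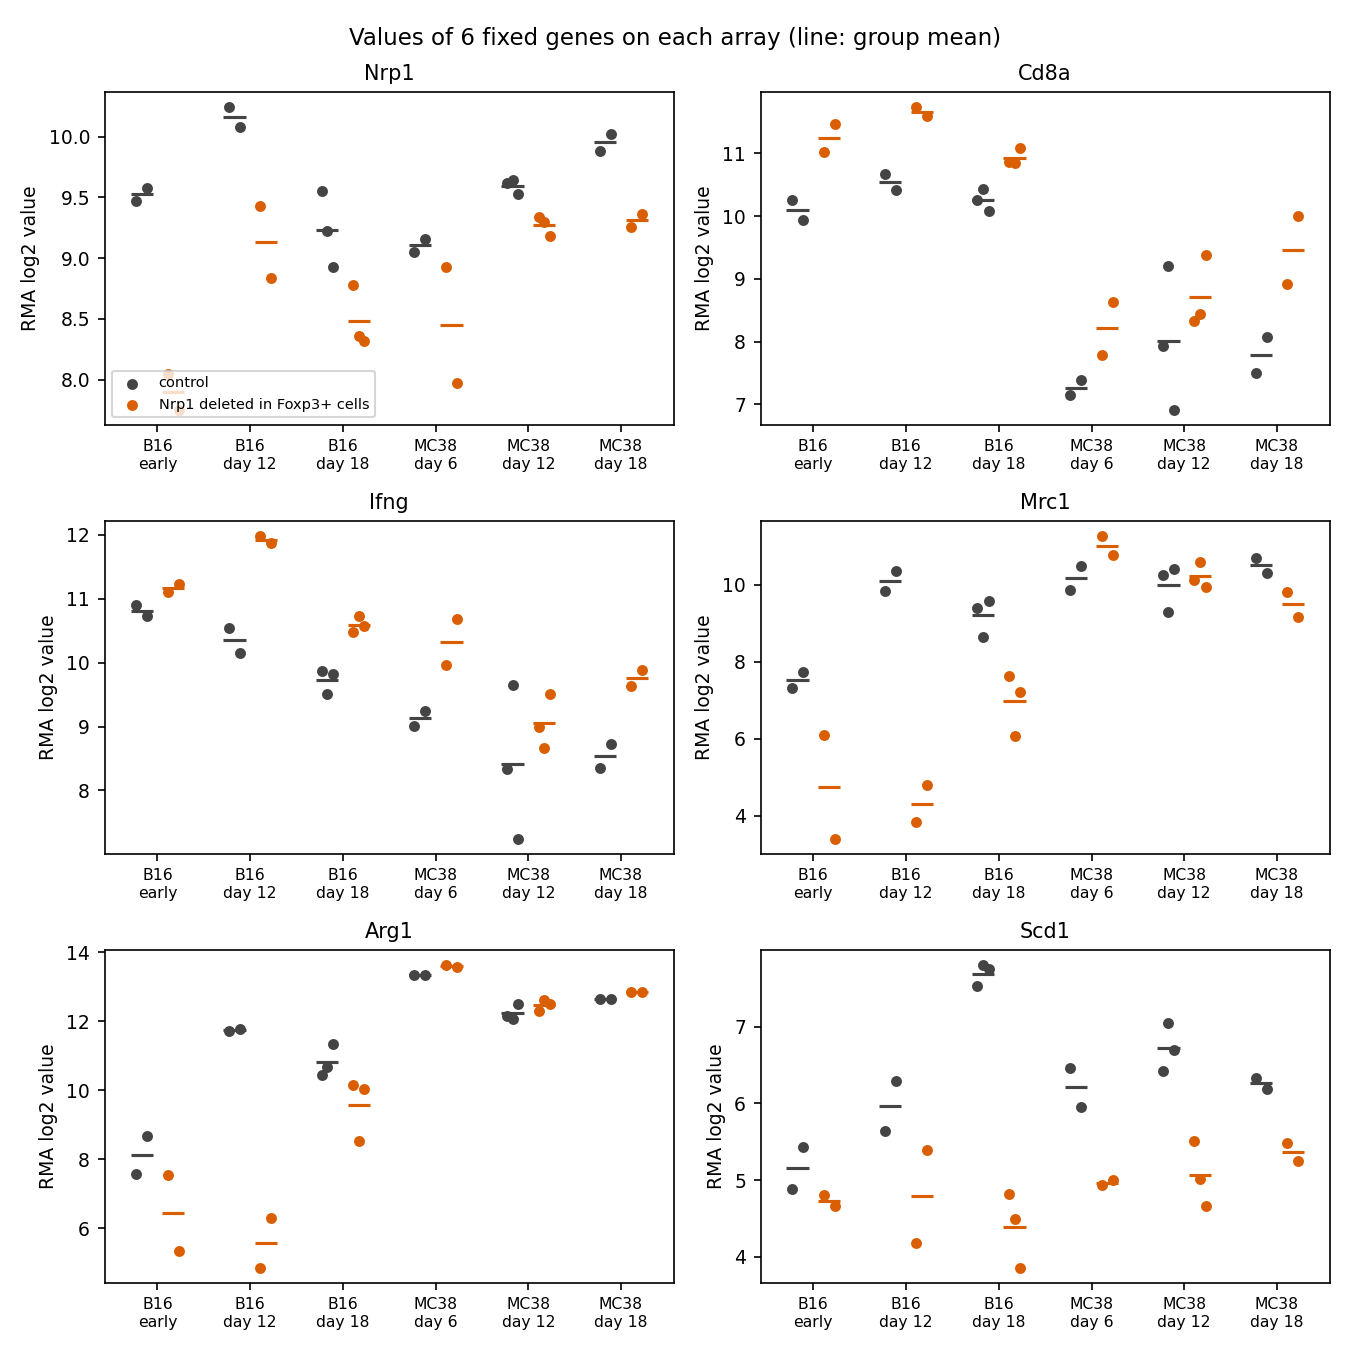
RMA log2 values (vertical axes) of 6 fixed genes on each of the 28 arrays, by tumour and day (horizontal axes), with control arrays in grey and Nrp1-deleted arrays in orange. Points are arrays and lines are group means. Nrp1 and Scd1 are lower and Cd8a and Ifng higher in the mean of the deleted arrays in all 6 settings, while Mrc1 and Arg1 are lower in the 3 B16 settings.

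The labels set control against Nrp1-deleted hosts, which asks how loss of Nrp1 from Treg changes the leukocytes of a tumour. Genes of CD8+ T cells rose. Cd8a, a chain of the CD8 co-receptor, rose by 1.04 and Ifng, the gene for interferon gamma, by 0.97 (adjusted permutation p = 0.00038 and 0.000317). Gzmb (granzyme B, 0.59), Prf1 (perforin, 0.92) and Pdcd1 (the inhibitory receptor PD-1, 1.02) rose too, and all 5 were higher in 6 of 6 settings. Mrc1, a mannose receptor of tissue macrophages, was lower by over 3-fold (-1.79, in 4 of 6 settings, adjusted permutation p = 0.00801), and Adgre1, the gene for the macrophage protein F4/80, fell by 0.97. Of the lipid genes, Scd1, a fatty acid desaturase, fell by 1.45 (adjusted permutation p = 9.5e-05, in 6 of 6 settings), and Fasn (fatty acid synthase, -0.23) and Acaca (acetyl-CoA carboxylase, -0.23) fell by little. The Acaca fall rests on the probe set chosen, since the mean over its probe sets was -0.03 (limma adjusted p = 0.78).

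Of the other fixed genes, Arg1 (arginase 1, -1.40, adjusted permutation p = 0.0537) and the scavenger receptor Cd36 (-0.58, p = 0.203) did not pass over the 6 settings by the same test. Cxcl9 (-0.09), Cd274 (PD-L1, 0.13), Nos2 (0.07), Cd163 (-0.03) and Xist (0.01) did not pass either, though without the B16 day 18 arrays limma called Cxcl9 lower (-0.26, adjusted p = 0.00824). In B16 alone, 13 of the 19 measured fixed genes passed, among them Cd8a (0.98), Ifng (0.93), Prf1 (0.91), Adgre1 (-1.58), Mrc1 (-3.59), Arg1 (-3.03), Cd36 (-1.57), Cd163 (-0.45), Scd1 (-1.63), Fasn (-0.21), Gzmb (0.60) and Pdcd1 (0.72). The exact permutation test there had 720 arrangements and a smallest p of 0.0028. The Cd163, Gzmb and Pdcd1 calls in B16 are not firm, since limma no longer made them without the B16 day 18 arrays (Cd163 -0.21, adjusted p = 0.578; Gzmb 0.60, adjusted p = 0.186; Pdcd1 0.77, adjusted p = 0.191) or with no variance trend (adjusted p = 0.0508, 0.0621 and 0.0695). A robust trend and the mean over probe sets ended the Gzmb and Pdcd1 calls too. Among B16 arrays, only control replicate 3 of day 18 (4.21) had a Cd163 value above 3.64, the median of all values. Cxcl9 in B16 was -0.19 and did not pass, and without the B16 day 18 arrays it was -0.66 (limma adjusted p = 0.000298). In MC38, 7 passed: Nrp1, Cd8a (1.11), Ifng (1.02), Pdcd1 (1.33), Scd1 (-1.27), Acaca (-0.31) and Arg1, which was higher there (0.24). The Acaca call in MC38 is not firm: limma no longer made it after cyclic loess (-0.21, adjusted p = 0.153), and the mean over its probe sets was above 0 (0.032, adjusted p = 0.818). Mrc1 did not pass in MC38 (0.01), nor did Prf1 (0.94), Gzmb (0.57), Fasn (-0.24), Adgre1 (-0.35), Cd163 (0.40), Cd36 (0.41) or Cd274 (0.34). The MC38 calls rest on few arrays: leaving out 1 array gave between 0 and 9 genes, and 0 without day 6 control replicate 1 or 2 by exact permutation.

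Across all genes, the 10 largest rises over the 6 settings were led by Mcpt8, a basophil protease (1.54 ± 0.28), and by genes of T cells and cytotoxic lymphocytes. These were Fasl (1.47 ± 0.16), Cd28 (1.41 ± 0.17), Bcl11b (1.38 ± 0.16), Lag3 (1.35 ± 0.22), Prkcq (1.30 ± 0.14), Gzmk (1.29 ± 0.23), Cd27 (1.27 ± 0.17) and Satb1 (1.24 ± 0.13), with Fam20a, a pseudokinase of the secretory pathway (1.34 ± 0.21). The largest falls were in the neutrophil chemokine Cxcl1 (-2.14 ± 0.32), Pf4, platelet factor 4 (-2.13 ± 0.23), and the dendritic cell chemokine Ccl17 (-2.10 ± 0.24). Plet1 (-1.97 ± 0.27), the endocytic adaptor Dab2 (-1.70 ± 0.18), Tm4sf1 (-1.95 ± 0.24), Serpinh1 (-1.91 ± 0.18), Ccn1 (-1.83 ± 0.17), Fermt2 (-1.71 ± 0.14) and Wwtr1 (-1.68 ± 0.16) fell as well. Serpinh1 encodes a collagen chaperone and Fermt2 the integrin adaptor kindlin-2. In limma, 4931 of 17097 genes passed an adjusted p of 0.05, 1874 higher and 3057 lower, and 213 of them differed by at least 2-fold. Without the B16 day 18 arrays, the count was 4036. With the melanocytic and fibroblast scores of each array as covariates, 16 genes passed, and the median SE was 3.62 times as wide.

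T cell, cytotoxic, inhibitory receptor and NK cell lists rose. Of the T cell list, 14 of 15 measured genes rose over all genes tested and 14 when adjusted over the list alone, with a mean of 0.96. Examples are Cd247 (1.22 ± 0.17) and Ubash3a (0.78 ± 0.10), a T cell receptor chain and a regulator of its signalling. All 15 cytotoxic lymphocyte genes rose by either adjustment (mean 0.90), among them Gzma (1.00 ± 0.13) and the transcription factor Tbx21 (1.15 ± 0.19). Of 9 inhibitory receptor genes, 8 rose over all genes and 9 adjusted over the list alone (mean 0.67), with Cd160 at 0.86 ± 0.11 and Havcr2, TIM-3, at 0.43 ± 0.07. Of 11 NK cell genes, 9 rose by either adjustment (mean 0.74), such as the receptors Klrc1 (1.09 ± 0.17) and Klrd1 (0.88 ± 0.12). The adjusted permutation p was 0.000127 for T cells, 7.6e-05 for the cytotoxic and for the inhibitory list, and 0.00038 for NK cells. Camera gave adjusted p = 1.69e-12, 2.35e-12, 2.47e-08 and 2.98e-08 in that order. None held with an estimated correlation, where the adjusted p = 0.117 for the T cell, cytotoxic and NK lists and 0.0917 for inhibitory receptors. The Treg list did not pass (0.22, adjusted permutation p = 0.108): 4 of its 12 genes rose, such as Izumo1r (0.60 ± 0.12), and 2 fell, Ebi3 (-0.88 ± 0.10) and Capg (-0.37 ± 0.06). The B cell list did not pass either (-0.04, adjusted permutation p = 0.685).

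Macrophage, MHC class II and dendritic cell lists fell in the mean over the 6 settings, but further in B16 than in MC38. The B16 effect minus the MC38 effect was -1.39 for macrophage and -1.62 for M2-like genes, and the macrophage list was at -0.145 in MC38. Of 15 macrophage genes, 14 fell over all genes, and 14 fell and 1 rose adjusted over the list alone (mean -0.84), among them the complement gene C1qc (-1.20 ± 0.13), Ms4a7 (-1.46 ± 0.15) and the growth factor receptor Csf1r (-0.75 ± 0.08). All 9 MHC class II genes fell (mean -0.87; H2-Ab1 -0.97 ± 0.10, Cd74 -0.84 ± 0.09). Of 18 M2-like macrophage genes, 11 fell over all genes and 13 adjusted over the list alone (mean -0.88), with Stab1 at -1.26 ± 0.12 and Folr2 at -1.31 ± 0.17. Of 10 genes of conventional type 1 dendritic cells, 6 and 7 fell by the 2 adjustments (mean -0.69; Batf3 -1.04 ± 0.11, Tlr3 -1.16 ± 0.09), and of 11 mature dendritic cell genes 7 fell and 1 rose by either (mean -0.80; Fscn1 -1.26 ± 0.11, Il12b -1.39 ± 0.16). The adjusted permutation p was 0.000142 for macrophages and for MHC class II, 0.00734 for the M2-like list, 0.00038 for type 1 and 0.000484 for mature dendritic cells. Camera passed all 5, the largest adjusted p being 7.73e-05 for type 1 dendritic cells. With an estimated correlation none passed (adjusted p = 0.191 for mature dendritic cells and 0.117 for the other 4). Monocyte (-0.36) and neutrophil lists (-0.26) did not pass (adjusted permutation p = 0.302 and 0.22). Markers of melanocytic cells moved with the falling lists: 13 of 13 fell (mean -0.75; Mitf -0.81 ± 0.09, Pmel -1.01 ± 0.13; adjusted permutation p = 0.0174, adjusted p = 0.117 with an estimated correlation). The melanocytic list was lower in 4 settings and higher in 2, and its B16 effect minus its MC38 effect was -1.49.

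Lipid synthesis lists fell in all 6 settings. Of 18 measured cholesterol synthesis genes, targets of SREBP2, 17 fell by either adjustment (mean -0.47; adjusted permutation p = 7.6e-05), including farnesyl diphosphate synthase Fdps (-0.75 ± 0.08) and squalene epoxidase Sqle (-0.79 ± 0.09). Of 14 SREBP1 fatty acid synthesis genes, 8 fell and 1 rose over all genes, and 9 fell and 2 rose adjusted over the list alone (mean -0.41, median -0.23; adjusted permutation p = 7.6e-05). The desaturases Fads2 (-1.56 ± 0.11), Scd1 (-1.45 ± 0.13) and Fads1 (-1.02 ± 0.08) fell most. Camera gave adjusted p = 1.24e-09 and 0.000907, and with an estimated correlation the adjusted p = 0.117 for each. Of 15 lipid uptake and efflux genes, 12 fell and 1 rose by either adjustment (mean -0.63; Apoe -1.35 ± 0.14; adjusted permutation p = 0.00453, camera adjusted p = 3.77e-05, adjusted p = 0.123 with an estimated correlation). The uptake list was lower in 5 settings and higher in 1, and fell mainly in B16 (B16 effect minus MC38 effect -1.17). Of 16 fibroblast genes, 9 fell by either adjustment (mean -0.85; Pcolce -1.26 ± 0.10, Serpinf1 -1.35 ± 0.11; adjusted permutation p = 7.6e-05, camera adjusted p = 2.98e-08, adjusted p = 0.0917 with an estimated correlation). In all, 22 of 38 lists passed by permutation, 20 by camera, 25 by fry, and 0 by camera with an estimated correlation (13 at an unadjusted p under 0.05).

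**Figure D2:**
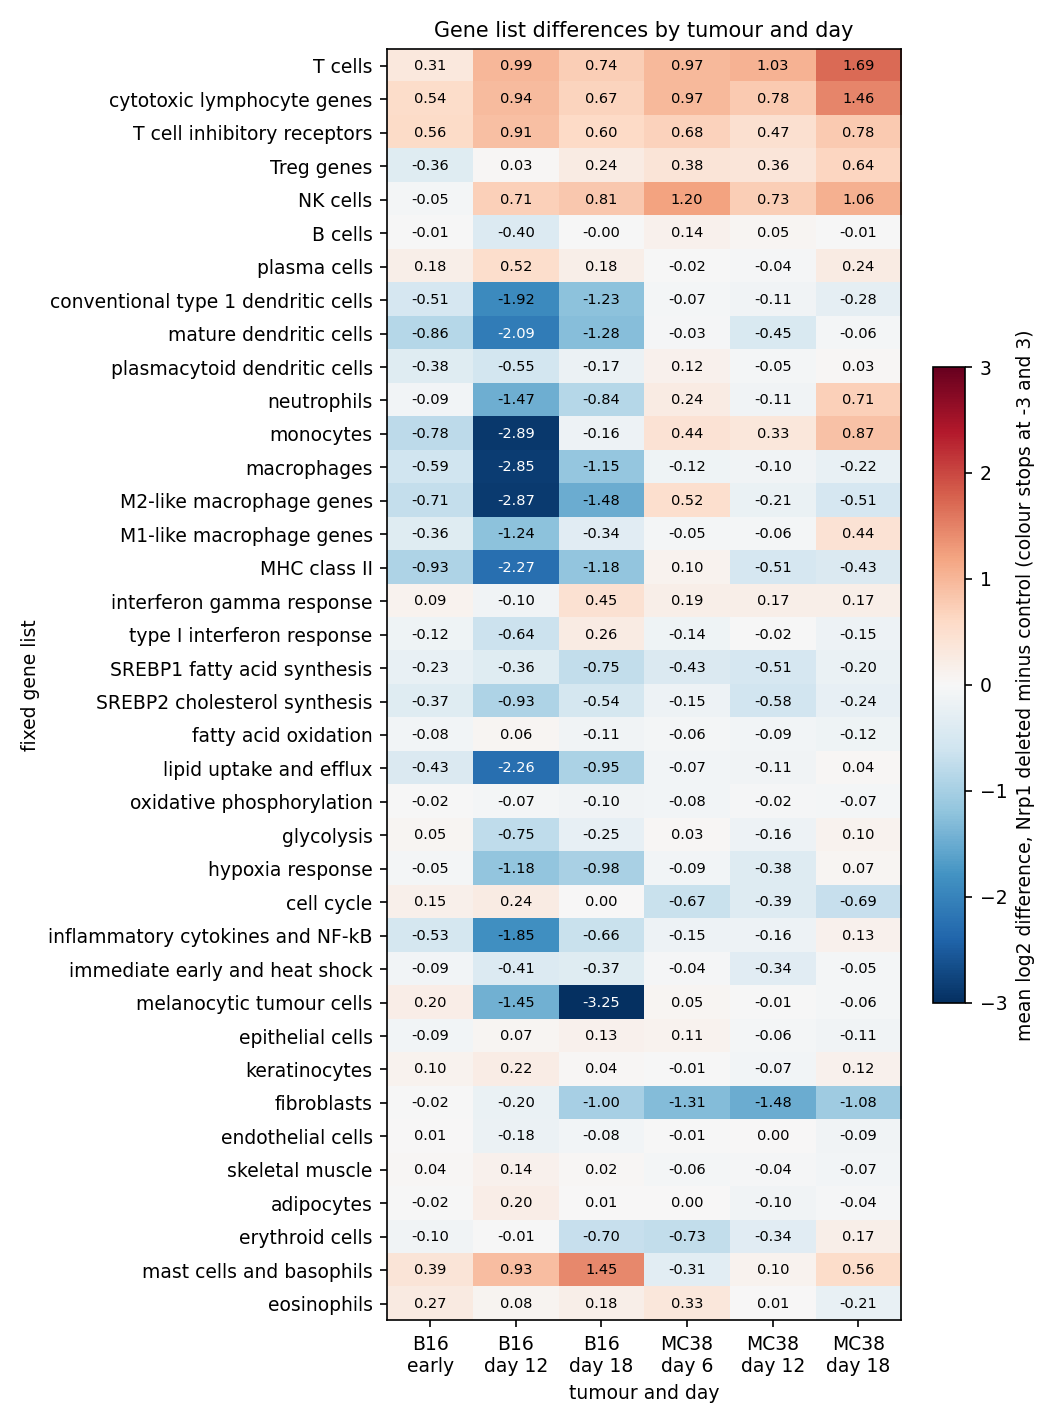
Mean log2 difference between Nrp1-deleted and control arrays for 38 fixed gene lists and the 6 settings of tumour and day. Lists run down the vertical axis, settings along the horizontal axis, red is higher and blue lower in Nrp1-deleted hosts, and the colour scale stops at -3 and 3. The T cell, cytotoxic and inhibitory receptor lists are positive in all 6 settings, and macrophage values run from -2.85 in B16 at day 12 to -0.10 in MC38 at day 12.

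In B16 tumours, loss of Nrp1 from Treg went with a fall of macrophage genes. Pf4 (-4.02 ± 0.33), the chemokine Cxcl1 (-3.90 ± 0.45), Mrc1 (-3.59 ± 0.32), Dab2 (-3.31 ± 0.25), the lectin Mgl2 (-3.19 ± 0.34), Ccl17 (-3.15 ± 0.34), Arg1 (-3.03 ± 0.29), the lectin Clec4n (-2.77 ± 0.23), the macrophage elastase Mmp12 (-2.75 ± 0.25) and Ccl22 (-2.74 ± 0.23) had the 10 largest falls. The largest rises included basophil genes, namely Mcpt8 (2.80 ± 0.39), the transcription factor Gata2 (1.81 ± 0.39) and histidine decarboxylase, Hdc (1.42 ± 0.38), and genes of antibody-secreting cells, Iglv1 (2.14 ± 0.45) and Jchain (1.64 ± 0.32). Lag3 (1.46 ± 0.31), the cytokine Il21 (1.43 ± 0.19), Spry1 (1.49 ± 0.17), Fam20a (1.93 ± 0.30) and the glutamate transporter Slc17a6 (2.37 ± 0.33) completed the 10. Limma called 3868 genes, 1758 higher and 2110 lower, and 574 of the 619 that differed at least 2-fold were lower. Without the B16 day 18 arrays the count was 2285, and Hdc no longer passed (1.05, adjusted p = 0.0562). With melanocytic and fibroblast scores as covariates it was 285, with a median SE 2.6 times as wide.

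In B16, 14 of 15 macrophage genes fell and 1 rose by either adjustment (mean -1.53), 15 of 18 M2-like genes fell (-1.69), all 9 MHC class II genes fell (-1.46), and 12 of 15 lipid uptake genes fell while 1 rose (-1.21). Of 10 type 1 dendritic cell genes, 7 fell over all genes and 8 adjusted over the list alone (-1.22). These 5 lists, and the melanocytic list, in which 13 of 13 genes fell (-1.50; without the B16 day 18 arrays -0.63, and 0.20 at the early day alone), held with an estimated correlation (adjusted p = 0.0315 for each of the 6). Their adjusted exact permutation p was 0.0106, but 0.0162 for lipid uptake and 0.0235 for the melanocytic list. Of 18 SREBP2 genes, 16 fell over all genes and 17 adjusted over the list alone (-0.61; adjusted exact permutation p = 0.0106, camera adjusted p = 4.73e-11, adjusted p = 0.0538 with an estimated correlation). Of 14 SREBP1 genes, 6 fell, and 7 adjusted over the list alone (-0.45; adjusted exact permutation p = 0.0106, camera adjusted p = 0.000493, adjusted p = 0.0844 with an estimated correlation). T cell genes rose: 9 of 15, and 12 adjusted over the list alone (0.68; adjusted exact permutation p = 0.0106, camera adjusted p = 1.95e-05, adjusted p = 0.361 with an estimated correlation), and 13 of 15 cytotoxic genes, 14 over the list alone (0.72; adjusted exact permutation p = 0.0106, camera adjusted p = 4.98e-06, adjusted p = 0.33 with an estimated correlation). Mast cell and basophil genes rose in 5 of 9 cases, and in 6, with 1 fall, adjusted over the list alone (0.93; adjusted exact permutation p = 0.0264, camera adjusted p = 0.0136, adjusted p = 0.367 with an estimated correlation).

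In MC38 tumours, collagen and matrix genes fell and T cell genes rose. The 10 largest falls were Col6a1 (-2.82 ± 0.18), Col6a2 (-2.72 ± 0.17), Col5a2 (-2.62 ± 0.20), Ccn1 (-2.53 ± 0.24), Col5a1 (-2.50 ± 0.17), Col3a1 (-2.18 ± 0.23), Thbs2 (-2.15 ± 0.19), Postn (-2.13 ± 0.18) and Dcn (-2.07 ± 0.16), most of them matrix genes, and Rhox5 (-2.05 ± 0.23), a homeobox gene. Bcl11b, a T cell transcription factor (2.01 ± 0.23), Cd28 (1.93 ± 0.23), Fasl (1.80 ± 0.22) and the NK receptor Klra8 (1.88 ± 0.30) rose most among lymphocyte genes. The other large rises were Tut4 (2.14 ± 0.27), Lncpint (1.98 ± 0.28), Dmkn (1.85 ± 0.32), Nr2c2 (1.85 ± 0.22), Mirt1 (1.81 ± 0.23) and Plcxd2 (1.80 ± 0.19). Tut4 encodes a terminal uridylyltransferase, and Lncpint and Mirt1 are long noncoding RNAs. Limma called 3300 genes, 1191 higher and 2109 lower, and 274 differed at least 2-fold. After cyclic loess the split was 1593 higher and 1369 lower. With melanocytic and fibroblast scores as covariates limma called 0 genes (1768 at an unadjusted p under 0.05), with a median SE 3.99 times as wide.

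Of 16 fibroblast genes, 9 fell over all genes and 11 adjusted over the list alone in MC38 (mean -1.29; adjusted exact permutation p = 0.0352, camera adjusted p = 1.83e-12, adjusted p = 0.0261 with an estimated correlation). T cell genes rose in 14 of 15 cases, and in 15 adjusted over the list alone (1.23; adjusted exact permutation p = 0.0396, camera adjusted p = 7.84e-17, adjusted p = 0.159 with an estimated correlation). Cytotoxic genes rose in 13 of 15 cases, and in 14 over the list alone (1.07; adjusted exact permutation p = 0.0396, camera adjusted p = 5.15e-15, adjusted p = 0.175 with an estimated correlation), and 9 of 11 NK genes rose by either adjustment (1.00; adjusted exact permutation p = 0.0396, camera adjusted p = 3.03e-11, adjusted p = 0.148 with an estimated correlation). Of 28 cell cycle genes, 26 fell over all genes and 28 adjusted over the list alone (-0.58; adjusted exact permutation p = 0.0396, camera adjusted p = 2.44e-15, adjusted p = 0.355 with an estimated correlation), such as Tk1 (-1.06 ± 0.12) and Bub1b (-0.85 ± 0.11). Of 14 SREBP1 genes, 8 fell and 1 rose, and 8 and 2 over the list alone (-0.38; adjusted exact permutation p = 0.0352, camera adjusted p = 0.019, adjusted p = 0.383 with an estimated correlation). Of 18 SREBP2 genes, 7 fell, and 10 over the list alone (-0.33; adjusted exact permutation p = 0.0352, camera adjusted p = 0.000203, adjusted p = 0.383 with an estimated correlation). Monocyte genes rose in 3 of 8 cases by either adjustment (0.55; adjusted exact permutation p = 0.0469, camera adjusted p = 0.000836, adjusted p = 0.383 with an estimated correlation). Macrophage genes were at -0.15, with 1 of 15 lower (adjusted exact permutation p = 0.0792, camera adjusted p = 0.754, adjusted p = 0.939 with an estimated correlation), M2-like genes at -0.07 (adjusted exact permutation p = 0.784), and melanocytic genes at -0.01 (p = 0.825 by the same exact test). These 3 lists did not pass, and camera gave the M2-like and melanocytic lists the opposite sign to their means.

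The difference of the B16 effect minus the MC38 effect asks whether loss of Nrp1 from Treg acts alike in both tumours. Macrophage genes fell further in B16: 14 of 15 differed by either adjustment, with a mean difference of -1.39. Of the others, 7 of 8 monocyte genes (-1.82), 12 of 15 lipid uptake genes, with 1 higher (-1.17) and 8 of 10 type 1 dendritic cell genes (-1.07) also lay lower in B16. The largest single differences were Pf4 (-3.79 ± 0.47), Chil4 (-3.77 ± 0.46), Mrc1 (-3.61 ± 0.45), Dmkn (-3.53 ± 0.46) and Cxcl1 (-3.52 ± 0.64) below 0, and Col6a1 (3.06 ± 0.25), Col6a2 (2.62 ± 0.23), Mcpt8 (2.53 ± 0.56), Col5a2 (2.16 ± 0.28) and Col5a1 (2.08 ± 0.25) above 0. The fibroblast list lay at the floor of the values in controls of early and day 12 B16 tumours, with little room to fall. The collagen differences above 0 cannot be told apart from this limit. All 28 cell cycle genes lay higher in B16 than in MC38 by either adjustment (0.71; adjusted permutation p = 0.0274, camera adjusted p = 2.69e-16, adjusted p = 0.138 with an estimated correlation). Camera passed 21 lists, the permutation test of the difference 8, and camera with an estimated correlation 7. The 7 were macrophages (adjusted p = 0.0265 with an estimated correlation, adjusted permutation p = 0.0592), MHC class II (0.037 and 0.0889), monocytes (0.0314 and 0.022), and type 1 dendritic cells, M2-like genes, lipid uptake and the melanocytic list (0.0265 and 0.0474 each). The T cell (-0.55; adjusted permutation p = 0.443, camera adjusted p = 0.000801, adjusted p = 0.56 with an estimated correlation) and SREBP1 lists (-0.06; adjusted permutation p = 0.835, camera adjusted p = 0.348, adjusted p = 0.693 with an estimated correlation) were not shown to differ by permutation. The permutation exchanges genotype labels within tumour and day, so it tests for no genotype effect in either tumour. An effect shared by the tumours widens its range and raises its p. A large p there, as for these 2 lists, does not show that the effects are alike. Limma called 2388 genes, 1154 above and 1234 below 0, and 2218 without the B16 day 18 arrays. Cyclic loess gave 621 above and 1570 below.

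Across 10095 genes above the median of all values, the B16 and MC38 effects had a Spearman correlation of 0.401, outside the range of -0.365 to 0.376 from 100 relabellings within tumour and day. Genes are not independent replicates. The B16 and MC38 effects share no array, though the B16 day 18 and MC38 day 12 arrays lie in the same set. Without the B16 day 18 arrays the correlation was 0.277, and some relabellings of those arrays gave values as large. Among called genes, 587 were higher and 567 lower in both tumours, where independent lists would share 122.5 and 260.3, and 66 and 71 went opposite ways, against 216.9 and 147.0. These expected counts treat genes as independent and were not set against relabellings, so the excess alone does not show shared effects.

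At the early B16 day, 76 genes passed, 26 higher and 50 lower. Mrc1 (-2.77 ± 0.59), Lad1 (-2.24 ± 0.46), the chemokine Ccl1 (-1.82 ± 0.35), Cd70 (-1.71 ± 0.31) and Nrp1 (-1.62 ± 0.23) fell most, and Slc17a6 (2.83 ± 0.60), Fam20a (2.54 ± 0.56), Ovol2 (1.77 ± 0.27), Dlg2 (1.59 ± 0.30) and Lancl3 (1.43 ± 0.26) rose most. Leaving out an array gave counts of 9 and 6 (control replicates 1 and 2), 294 and 0 (deleted replicates 1 and 2; for the 0, limma had 683 at an unadjusted p under 0.05), so this day has no firm list of genes. At day 12 in B16, 2900 genes passed, 1333 higher and 1567 lower. The largest falls were Pf4 (-6.59 ± 0.61), Arg1 (-6.18 ± 0.53), Dab2 (-6.17 ± 0.47), Mrc1 (-5.78 ± 0.59) and Cxcl1 (-5.52 ± 0.83). The monocyte list was at -2.89, the M2-like list at -2.87, the macrophage list at -2.85 and the melanocytic list at -1.45. Jchain (3.99 ± 0.59), Iglv1 (3.86 ± 0.83), Mcpt8 (3.16 ± 0.72), Slc17a6 (2.90 ± 0.60) and Spry1 (2.64 ± 0.32) rose most. Leaving out control replicate 1 or 2 or deleted replicate 1 gave 1894, 1802 and 1841 genes. At day 18 in B16, 3217 genes passed, 1289 higher and 1928 lower. Melanocytic genes fell furthest: the list of 13 was at -3.25, with the pigment transporter Slc45a2 at -4.24 ± 0.28. Pf4 (-4.16 ± 0.50), Tm4sf1 (-3.97 ± 0.51), Cxcl1 (-3.91 ± 0.68) and Syngr1 (-3.89 ± 0.40) were the next largest falls, beside a macrophage list at -1.15. The rises were led by Mcpt8 (3.87 ± 0.59), the type 2 cytokine Il4 (3.0 ± 0.60), Gata2 (2.85 ± 0.59) and Il6 (2.50 ± 0.40) and the IgE receptor chain Fcer1a (2.41 ± 0.63).

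At day 6 in MC38, 508 genes passed, 168 higher and 340 lower. The chemokine Ccl24 (2.71 ± 0.72), the NK receptors Klra8 (2.29 ± 0.54) and Klrb1c (1.90 ± 0.43), Tut4 (2.36 ± 0.49) and Nr2c2 (1.89 ± 0.40) rose most, and Col5a1 (-3.22 ± 0.32), Cd34 (-2.79 ± 0.38), Rhox5 (-2.78 ± 0.43), Cald1 (-2.64 ± 0.43) and Col6a1 (-2.63 ± 0.32) fell most. The count was 59, 179 and 280 without control replicate 1, control replicate 2 and deleted replicate 2, and after cyclic loess 248 of 447 genes were higher. At day 12, 1468 genes passed, 635 higher and 833 lower, with Col6a2 (-3.52 ± 0.25), Col6a1 (-3.21 ± 0.26), Col5a2 (-3.13 ± 0.29), Col3a1 (-2.94 ± 0.35) and Ccn1 (-2.90 ± 0.36) as the largest falls and Lncpint (2.27 ± 0.42), Nr2c2 (2.15 ± 0.33), Bcl11b (1.87 ± 0.34), Kansl1 (1.85 ± 0.25) and Kcnq1ot1 (1.84 ± 0.27) as the largest rises. Without control replicate 3 the count was 733, and without deleted replicate 1 or 3 it was 873, while cyclic loess gave 760 higher and 583 lower. At day 18, 917 genes passed, 534 higher and 383 lower. Dmkn (3.53 ± 0.59), the cytokine Il6 (3.17 ± 0.49), granzyme K, Gzmk (2.84 ± 0.60), Bcl11b (2.78 ± 0.42) and Plcxd2 (2.66 ± 0.34) rose most, and Cbr2 (-2.70 ± 0.69), Col6a1 (-2.63 ± 0.32), Col5a2 (-2.30 ± 0.36), Ccn1 (-2.30 ± 0.44) and Klra17 (-2.25 ± 0.54) fell most. Leaving out any of the 4 arrays gave between 262 and 315 genes, and cyclic loess 654 higher and 260 lower.

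The genotype effect at day 18 was set against that at the first day. In B16, 829 genes differed, 232 above and 597 below 0. The largest falls were pigment and other genes, Slc45a2 (-4.51 ± 0.44), Kcnj13 (-4.50 ± 0.38), Sparcl1 (-4.44 ± 0.48), Rab38 (-4.24 ± 0.43) and Gsta4 (-4.12 ± 0.45), of which Slc45a2 and Rab38 act in melanosomes. The largest rises were the cytokine genes Il4 (3.33 ± 0.95), Il6 (2.64 ± 0.63) and Il2 (2.34 ± 0.47), with Igk-V21 (2.32 ± 0.34) and Bach2 (2.01 ± 0.33). The count was 463, 503 and 548 without early control replicate 1, early control replicate 2 and early deleted replicate 1. In MC38, 14 genes differed: B3gnt5 (2.20 ± 0.41), Ppp1r10 (1.49 ± 0.26), Fosl2 (1.42 ± 0.26), Rybp (1.40 ± 0.26) and Nkrf (1.37 ± 0.23) were the largest rises, and the chemokine Ccl8 (-3.49 ± 0.65), the lymphocyte receptor Slamf6 (-1.68 ± 0.30) and Eya4 (-1.52 ± 0.25) fell. These calls are not firm, since leaving out any of the 8 arrays gave between 0 and 122 genes.

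Over time in MC38, with genotypes averaged, eosinophil genes were lower at day 18 than at day 6. Ccl24, an eosinophil chemokine (-5.51 ± 0.51), the lectin Mgl2 (-3.25 ± 0.45), Timp1 (-3.02 ± 0.29), G0s2 (-2.99 ± 0.36), Alox15, a lipoxygenase (-2.60 ± 0.25), and the neutrophil genes Stfa2l1 (-2.57 ± 0.38) and S100a9 (-2.55 ± 0.61) fell, with Flrt3 (-2.93 ± 0.45), F7 (-2.89 ± 0.24) and Pgf (-2.78 ± 0.27). The adhesion gene Cadm1 (4.31 ± 0.19), the guanylate-binding protein gene Gbp2b (3.91 ± 0.42), granzyme F, Gzmf (3.15 ± 0.79), and Gpr31b (3.0 ± 0.25), Pgbd5 (2.74 ± 0.25), Klra17 (2.70 ± 0.38), Dnase1l3 (2.30 ± 0.32), Col14a1 (2.29 ± 0.25), Myh10 (2.24 ± 0.31) and Tnfsf13b (2.24 ± 0.20) rose most. Limma called 2196 genes, 1249 higher and 947 lower, and 1273 without deleted replicate 2 of day 6.

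Of 5 eosinophil genes, 4 were lower at day 18 by either adjustment (mean -1.16; camera adjusted p = 2.15e-06, adjusted p = 0.0196 with an estimated correlation), such as Siglecf (-1.43 ± 0.24; in control mice alone -1.01, adjusted p = 0.072). Of 28 cell cycle genes, 19 rose over all genes and 23 adjusted over the list alone (0.58; camera adjusted p = 4.02e-13, adjusted p = 0.343 with an estimated correlation; Tk1 1.01 ± 0.16). Of 14 neutrophil genes, 5 and 8 fell by the 2 adjustments (-1.05; camera adjusted p = 4.25e-06, adjusted p = 0.196 with an estimated correlation), and of 11 mature dendritic cell genes 7 and 8 (-0.98; camera adjusted p = 3.54e-08, adjusted p = 0.196 with an estimated correlation; Ccl22 -1.93 ± 0.30). Of 18 M2-like genes, 7 fell and 1 rose, and 8 and 1 over the list alone (camera adjusted p = 4.16e-05, adjusted p = 0.343 with an estimated correlation), but in control mice alone the list did not pass camera (-0.48, adjusted p = 0.265). T cell genes fell in 5 of 15 cases, 8 over the list alone (-0.67; camera adjusted p = 4.16e-05, adjusted p = 0.467 with an estimated correlation), and MHC class II genes rose in 5 of 9, 8 over the list alone (0.49; camera adjusted p = 0.000711, adjusted p = 0.45 with an estimated correlation). In control mice alone the means were -0.88 for eosinophil, 0.59 for cell cycle, -1.29 for neutrophil, -0.96 for mature dendritic cell, -1.03 for T cell and 0.75 for MHC class II genes. The eosinophil list alone among the 17 that camera passed held with an estimated correlation.

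In B16, day 12 against the early day was added after the data were examined, because it lies inside a set of arrays. Interferon genes rose, and myeloid genes rose in the mean of both genotypes, mostly through the controls. The largest rises were Bcl11a (2.54 ± 0.31), Cd200r1 (2.49 ± 0.15), Vcan (2.32 ± 0.46), Il6 (2.31 ± 0.35), Nxpe4 (2.07 ± 0.28), Rgs18 (2.03 ± 0.41), Iglv1 (1.99 ± 0.59) and Rassf4 (1.92 ± 0.19), with Ciita, the activator of MHC class II genes (1.95 ± 0.22), and Usp18, an interferon-induced protease (1.93 ± 0.16). The Notch target Nrarp (-3.04 ± 0.24), the hypoxia-inducible factor Epas1 (-2.37 ± 0.31) and the transcription factor Myb (-1.70 ± 0.24) fell, with Sult2b1 (-2.32 ± 0.25), Taf4b (-2.01 ± 0.16), Jmy (-1.95 ± 0.17), Lmna (-1.90 ± 0.20), Ramp3 (-1.75 ± 0.21), Samd11 (-1.74 ± 0.23) and Zfp472 (-1.73 ± 0.15). In control mice alone, Iglv1 was 0.17 and Epas1 -1.02, and neither passed. Of 19 type I interferon genes, 16 rose over all genes and 17 adjusted over the list alone (mean 0.84; camera adjusted p = 5.81e-14, adjusted p = 0.417 with an estimated correlation; Ifit2 1.53 ± 0.14). Interferon gamma response genes rose in 12 of 19 cases, 13 over the list alone (0.50; camera adjusted p = 1.39e-06, adjusted p = 0.513 with an estimated correlation; Cxcl9 1.03 ± 0.15), monocyte genes in 7 of 8, 8 over the list alone (1.26; camera adjusted p = 1.62e-05, adjusted p = 0.442 with an estimated correlation), and macrophage genes in 8 of 15 by either adjustment (0.63; camera adjusted p = 2.66e-05, adjusted p = 0.513 with an estimated correlation). In control mice alone the monocyte list rose by 2.32 and the macrophage list by 1.76, while in deleted mice their mean scores went from 7.76 to 7.97 and from 7.85 to 7.35. Cell cycle genes fell in 16 of 28 cases, 22 over the list alone (-0.45; camera adjusted p = 1.61e-08, adjusted p = 0.513 with an estimated correlation). Melanocytic genes fell in 6 of 13, 8 over the list alone (-0.64; camera adjusted p = 0.000869, adjusted p = 0.513 with an estimated correlation), but in control mice alone the list mean was above 0 (0.185). There, type I interferon genes were at 1.10, interferon gamma response genes at 0.60 and cell cycle genes at -0.50. Limma called 3968 genes, 2247 higher and 1721 lower.

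Day 18 against the early day in B16 crossed sets of arrays, so day and set cannot be told apart, and the median over all genes was -0.27. Macrophage and type I interferon genes were higher and the Notch target Nrarp lower, while melanocytic genes were higher in control mice only. Vcan (3.16 ± 0.42), Arg1 (2.91 ± 0.34), Dab2 (2.90 ± 0.30), Mmp12 (2.88 ± 0.30), Ciita (2.67 ± 0.20), carbonic anhydrase 9, Car9 (2.65 ± 0.17), and Iglv1 (2.60 ± 0.53), Chil3 (2.54 ± 0.33), Tfec (2.51 ± 0.23) and Clec4n (2.50 ± 0.28) rose most, and Nrarp (-4.59 ± 0.22), Sult2b1 (-3.43 ± 0.23), Cpsf7 (-2.94 ± 0.14), Frat2 (-2.72 ± 0.17), Myb (-2.69 ± 0.22), Taf4b (-2.58 ± 0.15), Phactr3 (-2.55 ± 0.21), Nr4a3 (-2.44 ± 0.21), Jmy (-2.42 ± 0.15) and Samd11 (-2.40 ± 0.21) fell most. In control mice alone Iglv1 was 1.54 and did not pass. Of 15 macrophage genes, 13 rose by either adjustment (0.99; camera adjusted p = 5.39e-11, adjusted p = 0.24 with an estimated correlation), of 13 melanocytic genes 11 (0.99; camera adjusted p = 7.02e-09, adjusted p = 0.24 with an estimated correlation; Sox10 2.27 ± 0.20), and of 19 type I interferon genes 13 rose and 1 fell (0.65; camera adjusted p = 1.48e-10, adjusted p = 0.24 with an estimated correlation). The melanocytic value averages opposite changes: the mean score went from 6.31 to 9.02 in controls and from 6.51 to 5.77 in deleted mice. Of 21 oxidative phosphorylation genes, 19 fell (-0.40; camera adjusted p = 4.16e-05, adjusted p = 0.24 with an estimated correlation), but the list mean was above 0 after cyclic loess (0.102). In control mice alone, macrophage genes were at 1.27, type I interferon genes at 0.46 and oxidative phosphorylation genes at -0.36. Limma called 10508 genes, 1959 higher and 8549 lower, against 3907 higher and 2944 lower after cyclic loess and 3739 and 3498 after centring on the 75th percentile.

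MC38 tumours were set against B16 tumours at days 12 and 18, with genotypes averaged. The CD45+ sorts of MC38 tumours held more RNA of macrophage and matrix genes, and those of B16 tumours more RNA of pigment and lymphocyte genes. Which cells held the pigment and matrix RNA was not tested, and the comparison crosses sets of arrays. The chemokine Cxcl14 (6.30 ± 0.12), the mast cell protease gene Mcpt2 (6.05 ± 0.19), Tmem119 (5.71 ± 0.14), Olfml3 (5.45 ± 0.18), Fcrls (5.28 ± 0.25) and Zmynd15 (5.13 ± 0.18), the collagens Col3a1 (5.03 ± 0.20) and Col14a1 (4.97 ± 0.16), Ms4a7 (4.71 ± 0.18) and Abcc3 (4.63 ± 0.17) were highest in MC38. The melanin synthesis genes Tyrp1 (-7.10 ± 0.17), Dct (-6.88 ± 0.17) and Tyr (-4.10 ± 0.19), the melanosome genes Mlana (-4.91 ± 0.20) and Pmel (-4.05 ± 0.15), and Klk1 (-4.38 ± 0.16), Jchain (-4.35 ± 0.27), Car6 (-3.73 ± 0.23), Nrn1 (-3.66 ± 0.21) and Syt4 (-3.58 ± 0.19) were highest in B16. Limma called 8390 genes, 3303 higher and 5087 lower in MC38, with 4451 and 4173 after centring on the 75th percentile. MC38 day 12 against B16 day 18, a comparison chosen after the data were examined, which lie in the same set but differ in day, gave 6870 genes, 3082 higher and 3788 lower.

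Of 15 macrophage genes, 14 were higher in MC38 by either adjustment (mean 2.33; camera adjusted p = 8.49e-13, adjusted p = 0.328 with an estimated correlation; Csf1r 2.61 ± 0.09, C1qc 3.71 ± 0.16). Of 16 fibroblast genes, 9 were higher (1.38; camera adjusted p = 2e-05, adjusted p = 0.328 with an estimated correlation; Dcn 4.56 ± 0.14), and of 9 MHC class II genes 8 were higher and 1 lower (1.34; camera adjusted p = 4.53e-06, adjusted p = 0.456 with an estimated correlation). All 15 T cell genes (-2.31; camera adjusted p = 1.39e-08, adjusted p = 0.456 with an estimated correlation; Cd5 -2.80 ± 0.20), all 15 cytotoxic genes (-1.80; camera adjusted p = 4.63e-07, adjusted p = 0.471 with an estimated correlation; Cd8a -2.36 ± 0.21) and 15 of 18 SREBP2 genes (-0.65; camera adjusted p = 0.000122, adjusted p = 0.456 with an estimated correlation) were lower in MC38. Of 13 melanocytic genes, 12 were lower and 1 higher (-3.04; camera adjusted p = 6.01e-08, adjusted p = 0.444 with an estimated correlation). In control mice alone the means were 1.41 for macrophage, 1.72 for fibroblast, 0.72 for MHC class II, -2.55 for T cell, -1.96 for cytotoxic, -0.81 for SREBP2 and -4.19 for melanocytic genes. Camera passed 15 lists, and with an estimated correlation 0 of 38 passed (3 at an unadjusted p under 0.05), against 28 by fry.

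**Figure D3:**
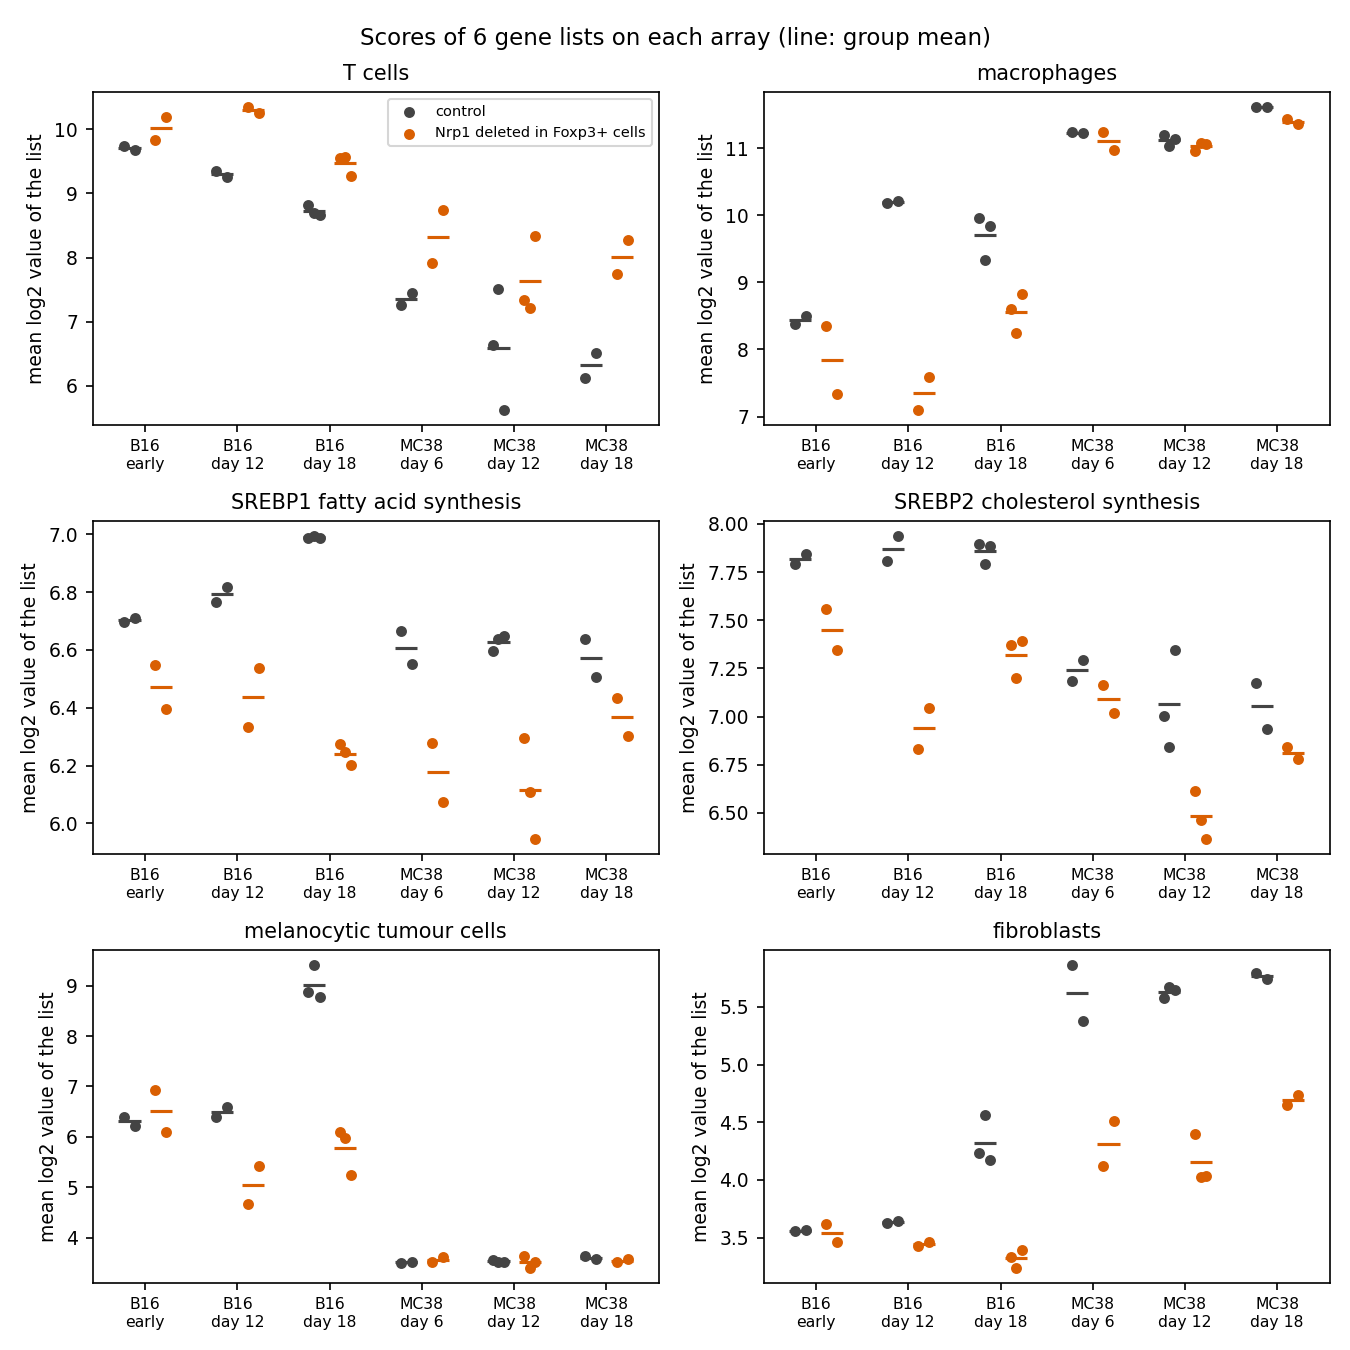
Mean log2 value of 6 gene lists (vertical axes) on each of the 28 arrays, by tumour and day (horizontal axes), with control arrays in grey and Nrp1-deleted arrays in orange. Points are arrays and lines are group means. The melanocytic score of B16 day 18 controls stands above all other groups, and fibroblast scores of MC38 controls above those of their deleted groups on all 3 days.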

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

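The tests of explanations in this part were chosen after the results were seen, while the counts over other splits of the arrays were planned. The results below stand out because a genotype effect differed between tumours or days by a test of that difference, or because they lie in probe sets unnamed here.

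The B16 effect differed from the MC38 effect at 2388 genes. Among the largest were Col6a1 (3.06), Col6a2 (2.62), Mcpt8 (2.53), Col5a2 (2.16) and Col5a1 (2.08) above 0 and Pf4 (-3.79), Chil4 (-3.77), Mrc1 (-3.61), Dmkn (-3.53) and Cxcl1 (-3.52) below 0. By camera, 19 lists lay lower in B16: T cells (-0.55), cytotoxic genes (-0.35), Treg (-0.49), NK cells (-0.51), type 1 dendritic cells (-1.07), mature dendritic cells (-1.23), plasmacytoid dendritic cells (-0.40), neutrophils (-1.08), monocytes (-1.82), macrophages (-1.39), M2-like genes (-1.62), M1-like genes (-0.75), MHC class II (-1.18), SREBP2 targets (-0.29), lipid uptake (-1.17), glycolysis (-0.31), hypoxia response (-0.60), inflammatory cytokines (-0.96) and melanocytic genes (-1.49). The cell cycle (0.71) and fibroblast lists (0.88) lay higher, though the fibroblast list had little room to fall in early and day 12 B16 tumours, where controls lay at the floor. With an estimated correlation, 14 of these 21 calls were lost, among them T cells (adjusted p = 0.56), and 8 lists passed by permutation. Of 100 splits that exchanged labels within tumour and day, 1, the real split, gave as many genes (highest other 889). These splits ask whether there is any genotype effect, so they cannot tell whether it differs between tumours. A split that exchanges all labels of 1 tumour turns the difference into a sum of the effects. It was not drawn, and the mean over all settings gave 4931 genes.

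Between day 18 and the early day, the B16 effect differed at 829 genes, with Il4 (3.33), Il6 (2.64), Il2 (2.34), Igk-V21 (2.32) and Bach2 (2.01) above 0 and Slc45a2 (-4.51), Kcnj13 (-4.50), Sparcl1 (-4.44), Rab38 (-4.24) and Gsta4 (-4.12) below 0. Chance cannot be excluded for this count, since 4 of 60 splits gave as many genes, with a highest of 2069. That split exchanges all labels on day 18 and so turns the difference of the effects into their sum, which points to an effect shared by the days. In MC38, 14 genes differed: B3gnt5 (2.20), Ppp1r10 (1.49), Fosl2 (1.42), Rybp (1.40) and Nkrf (1.37) above 0 and Ccl8 (-3.49), Slamf6 (-1.68) and Eya4 (-1.52) below 0 are named. The 18 splits there are too few for a share under 0.05, 4 gave as many genes, and the highest other count, 1983, again came from exchanging all day 18 labels.

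The pattern of melanocytic genes at B16 day 18 is a candidate case of tumour-cell RNA carried into the sort. All 13 of 13 members of the list were lower in the deleted group, whose mean score was 5.77 against 9.02 in controls, although the CD45 gate should remove tumour cells. The fall of all members restates the pattern and cannot tell carry-over from other causes. A difference in scaling is argued against, since the T cell list, of like level in controls (8.73), did not fall there (0.74), and its effect minus the melanocytic effect was 3.987 ± 0.437 (SE). Melanocytic RNA held by macrophages in equal measure on days 12 and 18 is argued against, since the melanocytic effect differed between those days by -1.80 ± 0.375 (SE) while the macrophage effect differed by 1.697 in the opposite direction. Those days lie in different sets of arrays, which limits this comparison. Carry-over, unequal uptake by leukocytes and a smaller or less pigmented tumour in deleted mice stay open, the last untested.

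The collagen pattern in MC38 was weighed next. Fibroblasts carried into the sort may explain it, although the CD45 gate should remove them: of the 16 fibroblast list members, 10 lay above the median of all values in MC38 controls, and all 10 were lower with deletion (Col3a1 at 10.42, Dcn at 8.70 and Sparc at 8.44 were the most abundant in controls). Against it, the other 6 lay below that median in the same controls, among them Col1a2 (2.77), Lum (3.10), Pdgfra (3.53) and Pdgfrb (3.36), and Col1a1 (3.84) lay just above it; values so near the floor exclude nothing, so fibroblasts stay open. That all 10 members fell restates the pattern and cannot tell fibroblasts from other sources of this RNA. Col3a1 fell at B16 day 18 too: it was 6.58, 8.10 and 6.47 on control arrays against 3.96, 3.56 and 4.25 on deleted arrays. Its fall was thus not confined to MC38. In controls of the other B16 days Col3a1 lay below 3.64, the median of all values. Fewer macrophages are argued against, since the fibroblast effect minus the macrophage effect in MC38 was -1.143 (exact permutation p = 0.00278, the smallest that 720 arrangements can give), with macrophages at -0.145. RNA of MC38 tumour cells stays open too: the fixed epithelial list had low mean scores, 3.33 to 3.83 over the MC38 groups, and did not pass in MC38 (-0.02, adjusted exact permutation p = 0.73), and no list was made for that line, while a change in the leukocytes themselves was not tested.

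Probe sets unnamed here changed as well: 3241 of 15588 passed over the 6 settings, 2209 higher and 1032 lower, or 20.8% against 25% of named probe sets.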

How the results depend on the processing

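The alternatives that leave out the B16 day 18 arrays, add scores as covariates or set MC38 day 12 against B16 day 18 were chosen after the data were examined, as were cyclic loess, centring on the 75th percentile and control mice alone where they concern gene lists, and the comparison of B16 day 12 with the early day. Counts of changed genes not named below stayed within 1.5 times the reported count. Counts of probe sets taken on their own were larger by construction, as more were tested: over all settings 10602, in B16 7191, in MC38 7484, between tumours 4457, at B16 day 12 4943, at B16 day 18 6523, at MC38 day 6 1083, at MC38 day 12 4289, at MC38 day 18 1904, for late against early in B16 1487, for B16 day 18 against early 28088, for MC38 day 18 against day 6 3720, for MC38 against B16 19271 and for B16 day 12 against early 7971. Leaving out the B16 day 18 arrays gave 2285 in B16 and a correlation between tumours of 0.277, for a cause not tested, and Pearson correlation gave 0.335. With melanocytic and fibroblast scores as covariates, limma called over all settings 16, in B16 285, in MC38 0 (1768 at an unadjusted p under 0.05), between tumours 0 (1626 at an unadjusted p under 0.05), in early B16 122, at B16 day 12 1330, at B16 day 18 0 (1460 at an unadjusted p under 0.05), at MC38 day 6 0 (1503 at an unadjusted p under 0.05), at MC38 day 12 0 (1466 at an unadjusted p under 0.05), at MC38 day 18 25, for late against early in B16 0 (1484 at an unadjusted p under 0.05) and for late against early in MC38 0 (1030 at an unadjusted p under 0.05). The median SE grew by 1.01 in early B16 and 1.04 for late against early in MC38, where the cause of the change was not tested. In the other comparisons it grew by factors of 1.59 to 3.99, as the scores follow the groups, so those counts cannot part the genotype from such RNA.

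Other counts moved as follows, and the cause was not tested. The mean of all probe sets per gene gave in early B16 42 and for late against early in MC38 3, no variance trend in early B16 33 and for late against early in MC38 2, array weights in early B16 271, at MC38 day 6 241, at MC38 day 18 2011 and for late against early in MC38 26, and a fit on only the groups compared in early B16 15, at B16 day 18 2141, at MC38 day 6 104, at MC38 day 12 723, at MC38 day 18 1862, for late against early in B16 544 and for late against early in MC38 33. A filter on dim genes gave for B16 day 18 against early 6798, cyclic loess for late against early in MC38 6 and for B16 day 18 against early 6851, and centring on the 75th percentile for late against early in MC38 4. With an estimated correlation, camera passed 0 lists over all settings (13 at an unadjusted p under 0.05), 6 in B16, 1 in MC38, 7 between tumours, 1 for MC38 day 18 against day 6, and 0 for B16 day 18 against early, MC38 against B16 and B16 day 12 against early (7, 3 and 3 at an unadjusted p under 0.05). Between tumours, the permutation of list scores passed 8 and of scaled scores 6, and fry passed 10 for MC38 day 18 against day 6 and 28 for MC38 against B16.

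As a block, replicate numbers gave at MC38 day 6 229, at MC38 day 18 517 and for late against early in MC38 0 genes (1060 at an unadjusted p under 0.05 for the 0 in limma). Residuals of 14 numbered pairs correlated at -0.405 to 0.252, with 3 pairs above 0.1, all at B16 day 18, so the numbers were not shown to pair the arrays over the whole series, but may do so at that day. With the block, limma no longer called Gzmb (adjusted p = 0.0674) and Pdcd1 (adjusted p = 0.0703) in B16, Fasn in MC38, Lancl3 in early B16, Klra8 and Klrb1c at MC38 day 6, Il4 (adjusted p = 0.0527) for late against early in B16, B3gnt5, Ccl8, Eya4, Fosl2, Nkrf, Ppp1r10, Rybp and Slamf6 for late against early in MC38.

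Scaling moved the share of higher genes by more than 10 points in MC38 (from 36.1% to 53.8% after cyclic loess), between tumours (48.3% to 28.3%), at MC38 day 6 (33.1% to 55.5%, and 47% by the 75th percentile), at MC38 day 12 (43.3% to 56.6%), at MC38 day 18 (58.2% to 71.6%), for MC38 against B16 (39.4% to 51.6% by the 75th percentile), and in B16 over time (18.6% to 57% and 51.7%). Late against early in MC38, a count of 14, went from 78.6% to 66.7% and 50%.

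Leaving out 1 array at a time gave these ranges of genes: over all settings 4472 to 5041, in B16 3030 to 4048, in MC38 2641 to 3428, between tumours 1882 to 2570, in early B16 0 to 294, at B16 day 12 1802 to 2157, at B16 day 18 2290 to 3309, at MC38 day 6 59 to 635, at MC38 day 12 733 to 1552, at MC38 day 18 262 to 315, for late against early in B16 463 to 1149, for late against early in MC38 0 to 122, for B16 day 18 against early 9087 to 10242, for MC38 day 18 against day 6 1273 to 2734, for MC38 against B16 7966 to 8380 and for B16 day 12 against early 3207 to 3377. A lone array left in a group is assumed to vary like the other groups. Lists passed by camera ranged over all settings 18 to 23, in B16 24 to 26, in MC38 11 to 12, between tumours 20 to 23, for B16 day 18 against early 15 to 17, for MC38 day 18 against day 6 16 to 18, for MC38 against B16 15 to 16 and for B16 day 12 against early 12 to 17. Fixed genes that passed ranged from 11 to 12 over all settings, 13 to 14 in B16 and 0 to 9 in MC38, where the count was 0 without day 6 control 1 or 2, 2 without day 12 deleted replicate 3 or day 18 control 1, 3 without day 12 control 1 or 3, day 6 deleted replicate 2 or day 18 control 2, and 4 without day 12 deleted replicate 1. The correlation between tumours ranged from 0.369 to 0.419.

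Among named genes, the call was lost without 1 array for Cd163, Cma1, Cpa3, Gzmb and Pdcd1 in B16; Acaca and Fasn in MC38; Ccl1, Cd70, Dlg2, Fam20a, Lad1, Lancl3, Mrc1, Nrp1, Ovol2 and Slc17a6 in early B16; Iglv1 and Mcpt8 at B16 day 12; Fcer1a at B16 day 18; Cald1, Ccl24, Klra8, Klrb1c, Nr2c2, Rhox5 and Tut4 at MC38 day 6; Cbr2, Ccn1, Gzmk and Klra17 at MC38 day 18; Il4 and Il6 for late against early in B16; B3gnt5, Ccl8, Eya4, Fosl2, Nkrf, Ppp1r10, Rybp and Slamf6 for late against early in MC38; Gzmf for MC38 day 18 against day 6; Iglv1 for B16 day 12 against early. Some values changed sign, and the cause was not tested. These were Cd163 over all settings (0.002), the list of M2-like macrophage genes in MC38 (0.013), the list of epithelial cells in MC38 (0.057), the list of melanocytic tumour cells in MC38 (0.108), the list of B cells over all settings (0.003) and the list of oxidative phosphorylation for B16 day 18 against early (0.102) under cyclic loess, Cd163 over all settings (0.155) and the list of SREBP1 fatty acid synthesis between tumours (0.088) under leaving out the B16 day 18 arrays, Xist over all settings (-0.016) and Acaca in MC38 (0.032) under mean of all probe sets per gene, the list of epithelial cells in MC38 (0.013) and the list of melanocytic tumour cells in MC38 (0.022) under each array centred on its 75th percentile, the list of melanocytic tumour cells in MC38 (0.001) under permutation of the scaled list score, the list of melanocytic tumour cells for B16 day 12 against early (0.185) under control mice alone. Over all arrays left out 1 at a time, Cd163 over all settings ran from -0.139 to 0.089, Xist from -0.037 to 0.06, and Mrc1 in MC38 from -0.103 to 0.12. The signal over background of the arrays limits calls in dim genes such as Foxp3.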

Other observations

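In B16, other lists moved beside the macrophage genes. Hypoxia response genes fell in 10 of 14 cases over all genes and 11 adjusted over the list alone (-0.74; adjusted exact permutation p = 0.0162, camera adjusted p = 8.25e-09, adjusted p = 0.0796 with an estimated correlation), among them Car9 (-1.62 ± 0.14) and Bnip3 (-0.88 ± 0.09). Of 13 inflammatory cytokine genes, 7 fell and 3 rose by either adjustment (-1.01; adjusted exact permutation p = 0.0235, camera adjusted p = 0.00174, adjusted p = 0.33 with an estimated correlation), and the monocyte chemokines Ccl7 (-2.35 ± 0.26), Ccl12 (-1.96 ± 0.20) and Ccl2 (-1.71 ± 0.21) fell. Hk2 (-0.80 ± 0.10), a glycolytic kinase, fell, though the glycolysis list did not pass by exact permutation (adjusted p = 0.0633; -0.32). The mast cell proteases Cpa3 (1.28 ± 0.34) and Cma1 (1.19 ± 0.34) rose, but without the B16 day 18 arrays neither passed in limma (Cpa3 1.08, adjusted p = 0.091; Cma1 1.09, adjusted p = 0.0959).

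Over the 6 settings, interferon gamma response genes rose in 8 of 19 cases, with 1 fall, and in 10 with 1 fall adjusted over the list alone (0.16; adjusted permutation p = 0.0149, camera adjusted p = 0.000402, adjusted p = 0.475 with an estimated correlation). Gbp7 (0.39 ± 0.07) and Nlrc5 (0.35 ± 0.07) rose and the chemokine Cxcl10 (-0.28 ± 0.07) fell. Of 15 fatty acid oxidation genes, 6 fell and 2 rose by either adjustment (-0.07; adjusted permutation p = 0.0163, camera adjusted p = 0.327, adjusted p = 0.622 with an estimated correlation), with Decr1 at -0.39 ± 0.05. Oxidative phosphorylation genes fell in 7 of 21 cases by either adjustment (-0.06; adjusted permutation p = 0.000665, camera adjusted p = 0.0614, adjusted p = 0.546 with an estimated correlation). The immediate early and heat shock list had a lower mean with deletion in 6 of 6 settings. Prdm1, a regulator of plasma cells and effector T cells, rose (0.50 ± 0.07).

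The tests of the lipid pattern below were chosen after the result was seen, and the splits that follow were planned except where noted. The SREBP1 and SREBP2 lists were lower in all 6 settings. In MC38, a colon carcinoma, the melanocytic list did not pass, so the SREBP1 fall there (-0.383, exact permutation p = 0.00278) does not bear on tumour-cell RNA in general. RNA of MC38 tumour cells stays open, as no list was made for that line. In B16, the SREBP2 fall shrank from day 12 to day 18 by 0.396 ± 0.175 (SE) while the melanocytic effect changed by -1.80. This argues only weakly against melanocytic RNA as the only cause of that fall. The SE is large beside the change, and those days lie in different sets of arrays. Melanocytic RNA stays open for SREBP1 in B16 (-0.391 ± 0.122 (SE) between those days). At the early day it cannot be told apart, with the SREBP2 effect minus the melanocytic effect at -0.568 ± 0.3 (SE). Fewer macrophages are argued against in MC38, where the SREBP1 effect minus the macrophage effect was -0.238 (exact permutation p = 0.0167), and as the only cause of the SREBP1 fall in B16, which grew between days 12 and 18 while the macrophage fall shrank by 1.697, but stay open for SREBP2 in B16, which shrank with it. The B16 part again compares days that lie in different sets of arrays. RNA of the collagen-expressing cells stays open in MC38 (SREBP1 minus fibroblast effect 0.905, exact permutation p = 0.00278), and cannot be told apart in early B16 (-0.209 ± 0.162 (SE)). At B16 day 12 the SREBP2 minus fibroblast effect was -0.736 ± 0.207 (SE). The fibroblast list lay at the floor in controls of both days, so little such RNA was there to lose. Col3a1 was 3.32 and 3.36 in B16 day 12 controls, against a mean of 10.42 in MC38 controls. The test was set to decide only where the list lay above the median of all values in controls, so it is undecided here. The low control values themselves argue against such RNA as the source of the SREBP2 fall at B16 day 12. At B16 day 18, where the fibroblast list was lower with deletion as in all 6 settings, it was not tested. Lower lipid synthesis in the leukocytes of deleted hosts, or a mix of these cell types, may explain the pattern and was not tested apart from them.

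Other splits of the arrays were compared with the real split. They were planned for each count except B16 day 12 against early, where they came with that added comparison. Over all settings, the real split gave 4931 genes and the highest of 100 splits otherwise 1572, in B16 3868 and 1999, and in MC38 3300 and 1621. In each of these 3 counts 1 split, the real one, gave as many genes. The same held for B16 day 18 against early (10508, highest other 4921) and MC38 against B16 (8390, highest other 6928). These counts are thus larger than chance splits of these arrays gave. No label says that replicates came from separate mice, so chance differences between mice are not excluded. The splits were too few for a share under 0.05 at B16 day 18 (10 splits, 3217 and 69), at MC38 day 12 (10 splits, 1468 and 122), for MC38 day 18 against day 6 (18 splits, 2196 and 834) and for B16 day 12 against early (18 splits, 3968 and 1075).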
